A study of Mus musculus with 6 samples.

How the data were processed

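RNA was sequenced from spermatogonia with bright or dim ID4-GFP fluorescence, called Bright and Dim here, of mouse pups at postnatal day 8 that carry the Id4-eGfp (LT11) transgene, in which green fluorescent protein reports on Id4. There were 3 Bright libraries, labelled high for Id4 expression, and 3 Dim libraries, labelled low. Total RNA was extracted with Trizol and the cDNA was primed with oligo d(T), so polyadenylated transcripts were read. The labels do not say whether the 3 libraries of a group came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical. The strand of the libraries is not given either, so antisense and overlapping genes cannot be told apart.

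Reads were aligned and quantified with TopHat2 2.1.1 and Cufflinks 2.2.1 per the submitters' processing notes, which name the genome build mm9 and give no parameters. The deposited table holds FPKM (fragments scaled to transcript length in kilobases and to library size) for 31918 Ensembl genes, of which 21968 are protein coding. The authors also deposited 4 comparison tables with a log2 ratio of FPKM, a p-value and a q-value for each gene, whose test settings are not stated. Of 31584 gene identifiers found in the GENCODE M21 annotation, 25568 (81.0%) had coordinates identical to those on GRCm38. The coordinates given here are therefore on GRCm38, although the notes name mm9, and the annotation columns may have been joined after alignment. There were 6271 genes at 0 in all 6 libraries, and no per-sample column was left unused.

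Read totals were not used here. Genes with FPKM of at most 0.3 showed steps in near whole-number ratios between libraries, and 47.8% to 56.5% of these ratios lay within 2% of a ratio of whole numbers up to 4. From the size of the step in single-transcript genes, the libraries were put at roughly 22400000, 29500000 and 35500000 reads on the FPKM scale for Bright 1, 2 and 3, and 26900000, 32400000 and 33900000 for Dim 1, 2 and 3. These are approximate depths. Whole reads could not be recovered gene by gene, so the planned count-based tests were not run and no counting intervals are given.

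The values were used as log2(FPKM + 1) without rescaling. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, which left 13416. Bright was compared with Dim in limma 3.58.1 (R 4.3.3) with empirical Bayes moderation, a mean-variance trend and robust estimation, with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method and genes under 0.05 were called. Log2 fold changes are Bright minus Dim on log2(FPKM + 1), so they are smaller than the ratio of mean FPKM for genes with low values. On simulated data with 13416 genes, of which 200 were changed in 3 against 3 libraries, the procedure recovered 59% of the genes changed by 1 on the log2 scale and 90% of those changed by 2. Of the simulated calls 3.9% were unchanged genes, and 0 changed genes were called with the wrong sign. The simulated noise was independent between libraries, with the SD of each gene taken from the 3 Dim libraries. It held no outlying library and no effect of the replicate number, so these rates may not hold for the real libraries.

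A total of 27 gene lists were fixed before the data were examined, along with the test, its threshold and the rule for naming genes. The lists covered the stem-cell-associated, undifferentiated, progenitor, differentiating and meiotic states, GDNF-responsive genes, feedback targets of MAPK and FGF signalling, retinoic acid response, Wnt targets, and ID and E proteins. They also covered S phase, G2/M, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, cholesterol synthesis, piRNA and transposon silencing, DNA methylation, and immediate early and heat shock genes. Markers of Sertoli, Leydig, peritubular myoid, stromal, endothelial, macrophage, erythroid and postmeiotic cells made up the remaining lists. The 23 lists with at least 5 tested members were tested with camera in limma, a competitive two-sided test with a preset inter-gene correlation of 0.01, and adjusted over the lists. Camera was also run with the correlation estimated from the data, and the directional test fry was run beside it. Calls for single members were counted with adjustment over all genes tested and with adjustment over the list alone.

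The genes named were 20 preset genes, the 12 genes with the largest fold change in each direction, and up to 4 members of each list. The largest genes had to pass the threshold, have a mean of at least 5 FPKM in the higher group and show no overlap between the groups, and unnamed gene models were left out. From each list the called members with the largest fold change were taken, or the 2 with the highest mean where none was called. Genes named outside this rule are said to be so, or belong to a small count. Some items that the rule would name are not reported here. Id4 was also compared by an exact two-sided permutation test.

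Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter of 5 FPKM, quantile normalization, median of ratios scaling, limma without trend, and a stricter threshold. The replicate number as a block, each library left out in turn, and the authors' q-value in place of the limma test were planned too. Leaving out genes over 4 times higher in Bright 3 than in the other Bright libraries, and estimating the correlation without Bright 3, were added after seeing the data. A fit with the replicate block but without both replicate 3 libraries was also run and was not kept, because it leaves 1 residual degree of freedom. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.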

Results

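Spermatogonia with bright (Bright) and dim (Dim) ID4-GFP fluorescence, the germ cells of the testis from which spermatogenesis starts, were profiled by RNA sequencing in 3 libraries each. ID4 is a helix-loop-helix protein that inhibits the binding of other such factors to DNA, and the green fluorescent reporter of the Id4-eGfp line gave the 2 groups. The comparison asks how germ cells with a high and a low level of Id4 differ at postnatal day 8. Genes with at least 1 FPKM numbered 13158, 12999 and 14209 in Bright 1, 2 and 3, and 13148, 13009 and 12954 in Dim 1, 2 and 3. Approximate depths lay between 22400000 and 35500000 reads. At these depths 1 read per kilobase of transcript stood for about 0.0282 to 0.0447 FPKM, so values near that level rest on few reads.

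Id4 itself (ENSMUSG00000021379, GRCm38 chromosome 13, 48261427 to 48264036, protein coding) was higher in every Bright library than in every Dim library. It measured 28.5, 42.7 and 39.7 FPKM in Bright 1, 2 and 3, and 3.75, 4.71 and 5.39 FPKM in Dim 1, 2 and 3. The means were 37.0 ± 7.51 and 4.62 ± 0.821 FPKM (SD, n = 3 each), an 8.0-fold ratio of the means. The log2 fold change was 2.75 with a standard error of 0.19 (limma adjusted p = 9.69e-05). The exact two-sided permutation test of these 6 values gave p = 0.1, the smallest that 20 arrangements allow.

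Across the transcriptome the groups differed in 3016 of 13416 genes tested. Of these, 1608 were higher in Bright and 1408 higher in Dim. The values of the groups did not overlap in 5517 genes (41.1%), where chance gives 10%. Libraries of a group correlated at r = 0.951 to 0.981 within Bright and 0.977 to 0.987 within Dim, across genes, and at 0.912 to 0.956 between groups. The first principal component held 56.3% of the variance and separated the groups. The second held 22.2% and set Bright 3, at -36.0, apart from Bright 1 at 18.4 and Bright 2 at 29.2. Bright 3 also carried markers of other testis cells, with the Leydig markers at a mean of 206.6 FPKM against 2.22 to 3.92 in the other 5 libraries. Without Bright 3, 2541 genes were called, 1418 higher in Bright and 1123 higher in Dim, and 2263 of the 3016 calls were kept. Without Dim 2 the count was 1957 and without Dim 3 it was 1973, the largest drops among the libraries left out, with 849 and 878 genes higher in Dim.

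Genes linked to the spermatogonial stem cell were higher in Bright. Of 18 tested members of the stem-cell-associated list, which includes Id4, 17 were higher in Bright and 0 in Dim by limma, and the same 0 was found at an unadjusted p under 0.05. The median log2 fold change was 2.78. Adjusted over the list alone, all 18 were higher in Bright. Without Bright 3 there were again 17 and 0, with Egr4 (adjusted p = 0.0203) gained and Cd9 (0.0514) lost, and Cd9 was also lost without Dim 1 (0.0545). Gfra1, the GDNF co-receptor (chromosome 19, 58235604 to 58455909), measured 83.3 ± 5.85 FPKM in Bright and 4.98 ± 2.03 in Dim (log2 fold change 3.87 ± 0.22 SE, adjusted p = 4.66e-05). Ret, the tyrosine kinase that signals with it, measured 115.9 ± 1.38 and 15.7 ± 2.66 FPKM (adjusted p = 3.12e-05). The transcription factors Etv5 (chromosome 16, 22381309 to 22439719) and Bcl6b measured 80.9 ± 6.94 and 57.9 ± 8.11 FPKM in Bright against 5.73 ± 1.41 and 6.12 ± 0.992 in Dim. Lhx1, a LIM homeobox factor, was at 17.9 ± 0.204 against 0.508 ± 0.12 FPKM, and T, the T-box factor brachyury, at 13.2 ± 2.23 against 0.227 ± 0.109. Eomes, also a T-box factor, was at 5.35 ± 1.25 against 0.296 ± 0.055 FPKM, and the RNA-binding protein gene Nanos2 at 4.49 ± 0.757 against 1.02 ± 0.297 (adjusted p = 0.00104). The list moved as a set by camera (adjusted p = 9.14e-20), but adjusted p = 0.166 with an estimated correlation.

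Genes linked to growth factor signalling were higher in Bright, and some of them are counted above. In the GDNF-responsive list 13 of 16 members were higher in Bright, and 0 were higher in Dim after adjustment over all genes, with 1 at an unadjusted p under 0.05. Adjusted over the list alone, 13 were higher in Bright and 1, Mycn, in Dim. The called members Id4, Gfra1, Ret, Etv5, Bcl6b, Lhx1, T, Cxcr4 and Tspan8 are also on the stem-cell-associated list. These lists are therefore not separate results, and Id4 reports on the sort itself. The list passed by camera (median log2 fold change 2.78, adjusted p = 4.29e-14) and with an estimated correlation (adjusted p = 0.0387). The neurofilament gene Nefm measured 33.2 ± 11.1 FPKM in Bright and 1.97 ± 0.696 in Dim, and the zinc finger factor Egr2 45.0 ± 3.14 and 3.91 ± 0.92. Of 15 feedback targets of MAPK and FGF signalling, 14 were higher in Bright and 0 in Dim, at an unadjusted p under 0.05 and adjusted over the list alone as well. Dusp6, a phosphatase that acts on ERK, was at 57.3 ± 7.73 FPKM in Bright and 4.39 ± 1.05 in Dim, and Spry4, an inhibitor of receptor tyrosine kinase signalling, at 12.2 ± 1.73 and 0.636 ± 0.0859. Etv4 was at 53.7 ± 9.03 and 7.43 ± 1.88 FPKM. The median of this list was 1.82 (camera adjusted p = 6.96e-12), and it also passed with an estimated correlation (adjusted p = 0.0387). Its members Ier3 and Egr1 stood at 49.2 and 153.3 FPKM in Bright 3, the library with markers of other cells, against 8.37 and 73.2 in Bright 1. Ier3 was called at adjusted p = 0.0485, a call kept without Bright 3 (0.00543) and lost without Bright 2, Dim 1, Dim 2 or Dim 3 (0.101, 0.183, 0.176 and 0.152). Without Bright 3, 12 members of the MAPK and FGF list were higher in Bright, with Spred1 (0.058) and Spred2 (0.105) lost, and the estimated correlation no longer gave a call for it or for the GDNF list (adjusted p = 0.168 for each).

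**Figure D1:**
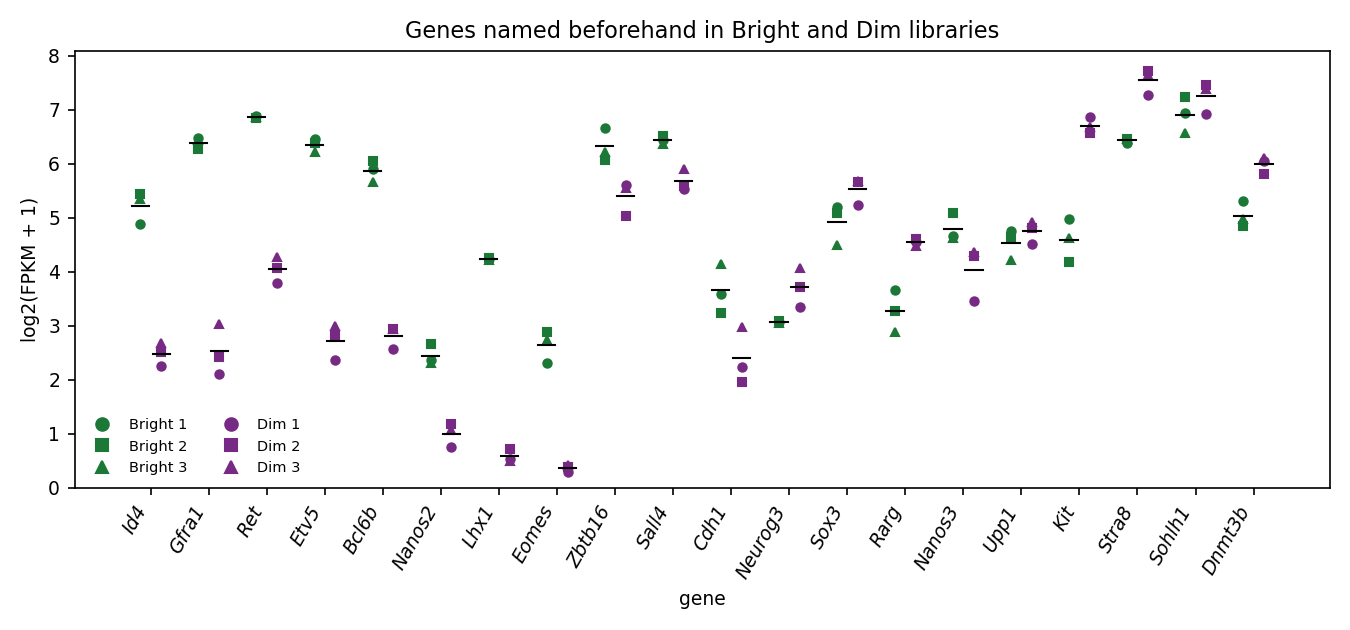
Expression of the 20 preset genes as log2(FPKM + 1) on the vertical axis, in 3 Bright libraries (green) and 3 Dim libraries (purple), with 1 marker shape per replicate number and a black line at each group mean. Gfra1, at 76.7 to 87.7 FPKM in Bright and 3.33 to 7.24 in Dim, lies far apart between the groups, while the values of Upp1 and Sohlh1 lie close together.

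The other genes with the largest excess in Bright belonged to several classes, and Foxc2, Tcl1 and Plvap were among the 17 called members of the stem-cell-associated list. Foxc2, a forkhead factor, measured 28.8 ± 4.64 FPKM against 2.02 ± 0.698 in Dim, and Tcl1, a coactivator of AKT, 72.6 ± 12.4 against 6.90 ± 1.86. Plvap, a protein of the diaphragms of endothelial fenestrae, was at 21.9 ± 2.89 against 1.39 ± 0.131 FPKM. Cbln2, a secreted synaptic organizer, was at 12.8 ± 1.53 against 0.563 ± 0.26 FPKM, and the membrane protein gene Tmem132e at 19.5 ± 0.388 against 1.47 ± 0.271. Adjusted p for these 5 genes lay between 2.72e-05 and 7.43e-05, and each kept its call with each library left out in turn. In the authors' table Foxc2 was not called (q = 0.312).

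The broader undifferentiated markers were mixed. Of 19 tested, 7 were higher in Bright, 2 higher in Dim and 10 did not pass; adjusted over the list alone, 8 were higher in Bright and 3 in Dim, as at an unadjusted p under 0.05. Zbtb16, which encodes PLZF, was at 80.2 ± 18.1 FPKM in Bright and 41.8 ± 8.83 in Dim (adjusted p = 0.015, and 0.0513 with no filter on low values). Sall4 was at 85.9 ± 4.41 and 50.6 ± 7.34 FPKM (adjusted p = 0.00673), and the integrin gene Itga6 at 82.7 ± 8.41 and 30.4 ± 3.46 (adjusted p = 0.000513). Zfp462 was at 57.4 ± 20.2 and 17.0 ± 4.27 FPKM and Pou5f1, which encodes OCT4, at 28.9 ± 7.03 and 10.9 ± 2.38. Cdh1, E-cadherin, was at 12.1 ± 4.28 and 4.51 ± 2.1 FPKM (adjusted p = 0.0227), a call lost without Bright 1, Bright 3, Dim 1 or Dim 2 (adjusted p = 0.0595, 0.067, 0.0955 and 0.0673). The members higher in Dim were Adgra3, at 14.3 ± 1.53 and 27.5 ± 2.25 FPKM, and Neurog3. Without Bright 3 the counts were 6 and 1. As a set the list did not pass (median 0.25, camera adjusted p = 0.19).

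Progenitor genes were split as well. Of 13 tested, 4 were higher in Dim, 1 higher in Bright and 8 did not pass; adjusted over the list alone, 6 were higher in Dim and 2 in Bright, as at an unadjusted p under 0.05. Neurog3, a basic helix-loop-helix factor, was at 7.41 ± 0.104 FPKM in Bright and 12.4 ± 3.4 in Dim (adjusted p = 0.0435). Its call was lost without Bright 1, Bright 2, Bright 3, Dim 2 or Dim 3 (adjusted p = 0.0943, 0.0756, 0.103, 0.0948 and 0.145). Rarg, the retinoic acid receptor gamma, was at 8.89 ± 2.65 and 22.4 ± 1.02 FPKM (adjusted p = 0.00281), and the homeobox gene Rhox13 at 19.14 ± 5.15 and 61.7 ± 18.4 (adjusted p = 0.00238). Bnc2, a zinc finger gene, was the member higher in Bright, at 63.3 ± 15.7 against 29.7 ± 1.49 FPKM. Neurog3 is also on the undifferentiated list, and Rhox13 and Dmrtb1, called higher in Dim as well, are also on the differentiating list. The counts of these lists therefore overlap. Sox3 at 30.1 ± 7.62 and 45.7 ± 7.68 FPKM (adjusted p = 0.0766), Nanos3 at 27.0 ± 5.29 and 16.1 ± 5.3 (0.0668) and Upp1 at 22.5 ± 4.41 and 26.1 ± 3.71 (0.441) did not pass, although Sox3 did without Dim 1 (0.0397). In the authors' table Sox3 was called (log2 ratio -0.80, q = 0.00232) and Neurog3 was not (q = 0.242). The list missed the threshold (median -0.35, camera adjusted p = 0.0859), and it passed without Bright 1 (0.0477) or Dim 1 (0.0264).

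Genes of differentiating spermatogonia were higher in Dim. Of 17 tested members, 10 were higher in Dim and 1 in Bright; adjusted over the list alone, 11 were higher in Dim and 1 in Bright, as at an unadjusted p under 0.05. Kit, the stem cell factor receptor whose appearance marks differentiating spermatogonia (chromosome 5, 75574916 to 75656722), was at 23.8 ± 6.64 FPKM in Bright and 104.0 ± 11.2 in Dim (log2 fold change -2.11 ± 0.20 SE, adjusted p = 0.000394). Stra8, a retinoic acid target, was at 85.5 ± 2.43 and 187.5 ± 30.2 FPKM (adjusted p = 0.00195), and the DNA methyltransferase gene Dnmt3b at 32.3 ± 5.67 and 63.1 ± 6.71 (adjusted p = 0.00404). Sohlh1, a helix-loop-helix factor of spermatogonial differentiation, was at 121.6 ± 27.9 and 154.4 ± 29.4 FPKM and did not pass (adjusted p = 0.285). The member higher in Bright was Ccnd2, cyclin D2, at 94.6 ± 10.9 against 17.9 ± 3.45 FPKM, which is also on the GDNF-responsive list. The median was -0.95 (camera adjusted p = 2.02e-05), with adjusted p = 0.376 with an estimated correlation.

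The largest excess in Dim was that of Prss50, a testis serine protease-like gene (chromosome 9, 110857967 to 110864629), at 0.732 ± 0.301 FPKM in Bright and 28.9 ± 15.2 in Dim (log2 fold change -3.96 ± 0.42 SE, adjusted p = 0.00118). Esx1, an X-linked homeobox gene, was at 3.28 ± 1.88 and 51.5 ± 17.3 FPKM. Dmrtb1, which encodes DMRT6 (chromosome 4, 107676290 to 107684230), was at 7.20 ± 2.75 and 98.2 ± 17.3 FPKM (log2 fold change -3.65 ± 0.27 SE, adjusted p = 0.000137). The T-box gene Tbx1 was at 1.29 ± 0.561 and 14.3 ± 4.28 FPKM, and the elongation factor gene Tcea3 at 2.40 ± 0.526 and 19.3 ± 4.0. The transcript AI854517 was at 1.29 ± 0.303 and 10.4 ± 2.07 FPKM, the galanin gene Gal at 0.839 ± 0.144 and 8.15 ± 1.6, Phlda3 at 4.39 ± 0.488 and 23.7 ± 2.17, and the RUNT factor Runx3 at 2.66 ± 0.931 and 15.0 ± 3.46. Cited1 was at 15.2 ± 10.2 and 75.2 ± 20.5 FPKM (adjusted p = 0.00951), a call lost without Dim 1 (0.0673) or Dim 2 (0.0573). Ly6k was at 2.16 ± 2.18 and 16.7 ± 8.42 FPKM (adjusted p = 0.0273), a call lost without Bright 1, Bright 2, Dim 1 or Dim 2 (0.0901, 0.112, 0.147 and 0.115).

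Meiotic and retinoic acid genes moved the same way in part. Of 25 tested meiotic genes 7 were higher in Dim and 0 in Bright, with 11 and 1 at an unadjusted p under 0.05; adjusted over the list alone, 9 were higher in Dim, and without Bright 3 there were 6. Prdm9, the histone methyltransferase that places recombination sites, was at 2.31 ± 0.182 FPKM in Bright and 14.9 ± 4.93 in Dim, and Meioc, a meiosis-specific RNA regulator, at 5.66 ± 1.3 and 28.0 ± 14.9. Mei1 and Ythdc2 were at 6.57 ± 1.89 and 8.06 ± 1.33 FPKM in Bright against 14.7 ± 2.88 and 17.7 ± 5.35 in Dim. The meiotic list passed by camera (median -0.27, adjusted p = 0.00494), with adjusted p = 0.618 with an estimated correlation. Without Bright 3 its median was -0.20 (camera adjusted p = 0.0326). Against the mean of Bright 1 and 2, the tested meiotic genes had a median log2 difference of -0.27 in Bright 3. Part of the shift of this list therefore rests on that library. Of 14 retinoic acid response genes 6 were higher in Dim and 1 in Bright; adjusted over the list alone, 6 were higher in Dim and 2 in Bright, as at an unadjusted p under 0.05. Crabp1, which binds retinoic acid in the cytoplasm, was at 73.6 ± 14.0 and 262.7 ± 72.7 FPKM (adjusted p = 0.00126), and Dhrs3, a retinaldehyde reductase, at 5.33 ± 2.45 and 1.71 ± 0.336 (0.0141, and 0.0566 without Dim 3). Without Bright 3, 7 were higher in Dim and 1 in Bright. Among the 6 higher in Dim, Kit, Stra8 and Crabp1 are also on the differentiating list and Rarg is on the progenitor list. The retinoic acid counts are therefore not separate from those lists. Crabp2 and Aldh1a2, also higher in Dim, lost their calls in 4 and 3 of the 6 fits with a library left out. The retinoic acid list passed (median -0.50, camera adjusted p = 0.0333), with adjusted p = 0.395 with an estimated correlation. This call was lost without Bright 1 (0.051), Bright 2 (0.0618) or Dim 3 (0.0514).

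**Figure D2:**
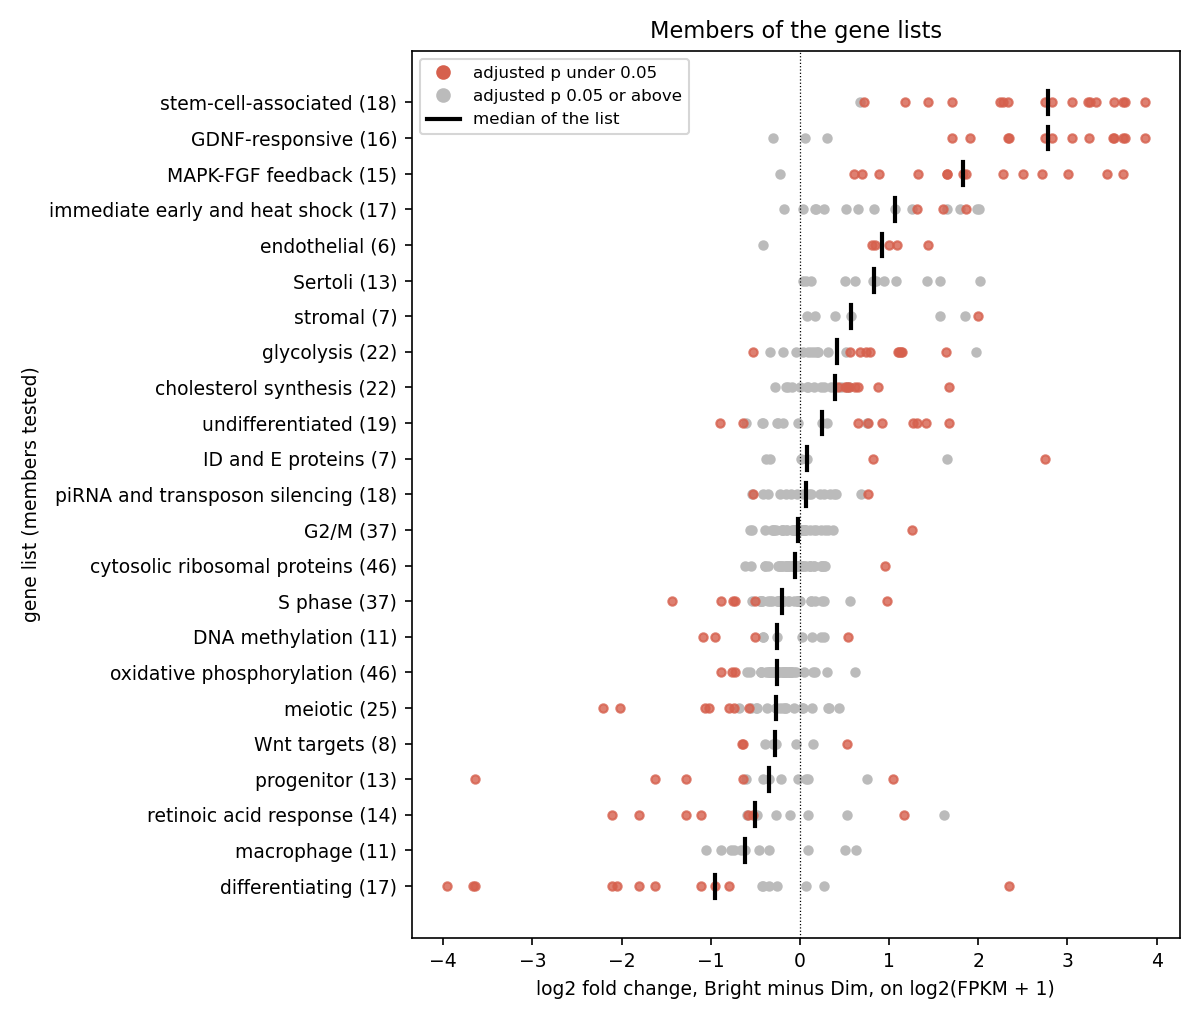
Log2 fold change of Bright minus Dim on log2(FPKM + 1), on the horizontal axis, for each tested member (points, red where adjusted p was under 0.05) of the 23 lists on the vertical axis, with a black bar at the median of each list. The stem-cell-associated and GDNF-responsive medians lie at 2.78 and the differentiating median at -0.95, with Ccnd2 at 2.35 as the red point to the right in that list.

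Metabolic genes showed smaller changes. In the glycolysis list 9 of 22 members were higher in Bright and 1, the monocarboxylate transporter gene Slc16a1, in Dim, with the same counts at an unadjusted p under 0.05 and adjusted over the list alone. Slc16a1 was at 22.9 ± 2.7 FPKM in Bright and 33.5 ± 5.91 in Dim (adjusted p = 0.049), a call lost without Bright 1, Bright 2, Bright 3, Dim 1 or Dim 3 (0.0526, 0.114, 0.116, 0.139 and 0.115), so the counts were 9 and 0 without Bright 3. Pdk1, a kinase that inhibits pyruvate dehydrogenase, was at 88.4 ± 8.06 FPKM in Bright and 27.7 ± 3.84 in Dim, and the pyruvate kinase gene Pkm at 334.3 ± 20.3 and 153.3 ± 33.8. Pfkp, a phosphofructokinase, was at 10.8 ± 0.64 and 4.37 ± 0.321 FPKM, and the glucose transporter gene Slc2a3 at 10.3 ± 0.735 and 4.26 ± 0.771. The glycolysis list passed (median 0.42, camera adjusted p = 0.00169), with adjusted p = 0.285 with an estimated correlation. Of 22 cholesterol synthesis genes 8 were higher in Bright and 0 in Dim, with 11 and 0 at an unadjusted p under 0.05, and 9 and 0 adjusted over the list alone. Without Bright 3 they were 8 and 1, with Tm7sf2 higher in Dim (0.0379). Msmo1, a sterol oxidase, was at 54.0 ± 5.31 and 28.9 ± 0.459 FPKM. Cholesterol synthesis passed as well (median 0.39, camera adjusted p = 0.002), with adjusted p = 0.285 with an estimated correlation. Of 46 oxidative phosphorylation genes 3 were higher in Dim and 0 in Bright, with 3 and 1 at an unadjusted p under 0.05, and 2 and 0 adjusted over the list alone. Without Bright 3 they were 2 and 1, with Ndufv1 higher in Bright (0.0449). Atp5f1, a subunit of ATP synthase, was at 135.1 ± 22.6 and 248.9 ± 31.6 FPKM and Uqcrc2, of complex III, at 58.4 ± 5.17 and 99.9 ± 3.99. The member Ndufv2, of complex I, was at 76.1 ± 21.2 and 125.1 ± 23.8 FPKM (adjusted p = 0.0451), a call lost without Bright 1, Bright 3, Dim 2 or Dim 3 (0.136, 0.127, 0.125 and 0.117). The list passed (median -0.26, camera adjusted p = 0.0156), with adjusted p = 0.772 with an estimated correlation. That call was lost without Bright 1 (0.242), Dim 2 (0.211) or Dim 3 (0.0613), and with quantile normalization (0.0501). The mean of the list was 138.9 and 156.7 FPKM in Bright 1 and Dim 1, and 212.5 and 239.4 in Bright 2 and Dim 2. In Bright 3 and Dim 3 it was 153.4 and 203 FPKM, so leaving out 1 library changes the balance of these levels.

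Cell cycle genes differed in part. Of 37 S phase genes 5 were higher in Dim and 1 in Bright, with 10 and 2 at an unadjusted p under 0.05 and 5 and 1 adjusted over the list alone. Without Bright 3 the counts were 4 and 1. The cyclin E2 gene Ccne2 was at 11.9 ± 0.708 FPKM in Bright and 34.3 ± 6.8 in Dim, the ribonucleotide reductase gene Rrm2 at 29.3 ± 5.79 and 54.8 ± 7.96, and the replication licensing gene Cdc6 at 17.9 ± 1.71 and 30.8 ± 2.18. Chaf1b, a chromatin assembly factor, was higher in Bright, at 41.0 ± 3.65 against 20.7 ± 5.12 FPKM. The S phase list passed (median -0.20, camera adjusted p = 0.0302), with adjusted p = 0.741 with an estimated correlation. It did not pass without Bright 3 (0.172) or Dim 3 (0.0584), nor with quantile normalization (0.113). Of 37 G2/M genes 1, Gas2l3, was higher in Bright and 0 in Dim, with 3 and 2 at an unadjusted p under 0.05, and the same 1 and 0 adjusted over the list alone. The G2/M list did not pass (median -0.03, camera adjusted p = 0.805).

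Several lists did not move as sets. For the ID and E proteins, Id4 and Tcf4 were the 2 of 7 higher in Bright, and 0 were higher in Dim at an adjusted or an unadjusted p under 0.05 and adjusted over the list alone (camera adjusted p = 0.146). Tcf4 was at 9.49 ± 3.63 and 4.78 ± 0.933 FPKM (adjusted p = 0.0459), a call kept only without Bright 2, and between 0.0684 and 0.122 without any 1 of the other 5 libraries. Without Bright 3 the counts turned, with 1 (Id4) higher in Bright and 2, Id1 and Id2, higher in Dim (log2 fold change -0.88 and -1.65, adjusted p = 0.0126 and 0.00264). Id2 was at 0.346, 0.455 and 18.41 FPKM in Bright 1, 2 and 3 and 3.36, 4.05 and 2.83 in Dim, and Id1 at 2.08, 1.69 and 7.88 against 4.12, 4.89 and 3.92. Of 8 Wnt targets, Notum at 0.975 ± 0.34 and 2.09 ± 0.317 FPKM and the cyclin D1 gene Ccnd1 at 43.4 ± 4.99 and 68.2 ± 3.71 were higher in Dim, and Apcdd1 at 5.42 ± 0.428 and 3.46 ± 0.0889 was higher in Bright, the same 2 and 1 adjusted over the list alone, with 3 and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.28). Notum lost its call without Bright 2, Bright 3, Dim 2 or Dim 3 (0.0578, 0.0661, 0.0971 and 0.0975), and Apcdd1 without Bright 1, Bright 2, Dim 1, Dim 2 or Dim 3 (0.0984, 0.0655, 0.0758, 0.101 and 0.0854). Of 11 DNA methylation genes, Dnmt3b, the 5-methylcytosine oxidase gene Tet3 and the glycosylase gene Tdg were higher in Dim and Mbd2, which binds methylated DNA, in Bright; adjusted over the list alone, 4 were higher in Dim and 1 in Bright, with 5 and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.346). The calls of Tet3, Tdg and Mbd2 were lost without Bright 2, Bright 3, Dim 1 or Dim 3, and those of Tdg and Mbd2 also without Dim 2, with adjusted p up to 0.0858, 0.12 and 0.0924. Of 18 genes of piRNA and transposon silencing, Morc1 was higher in Bright, at 55.7 ± 6.34 against 32.3 ± 1.85 FPKM, and Pld6 in Dim, at 19.9 ± 3.42 against 28.9 ± 1.67; adjusted over the list alone only Morc1 was called, and 4 were higher in each group at an unadjusted p under 0.05 (camera adjusted p = 0.656). Pld6 lost its call without Bright 2, Bright 3, Dim 1, Dim 2 or Dim 3 (0.0702, 0.085, 0.0548, 0.105 and 0.135). Without Bright 3, 3 of these genes were higher in Bright, with Tdrd5 (0.0373) and Asz1 (0.0453) gained, and 0 in Dim. Of 46 cytosolic ribosomal protein genes 1, Rps4x, was higher in Bright, 0 in Dim at an adjusted or an unadjusted p under 0.05, and 0 were called adjusted over the list alone, with 1 at an unadjusted p under 0.05. Rps4x was at 204.8 ± 46.8 and 105.5 ± 23.8 FPKM (adjusted p = 0.0213, lost at 0.0739 without Bright 3 and 0.053 without Dim 3). The ribosomal list did not pass (camera adjusted p = 0.805), though it did without Bright 2 (0.0448) or Dim 1 (0.0426). Its mean was 823 and 792 FPKM in Bright 1 and Dim 1, and 1325 and 1365 in Bright 2 and Dim 2. In Bright 3 and Dim 3 it was 891 and 1086 FPKM. Leaving out 1 library therefore changes the balance of these levels between the groups.

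Immediate early and heat shock genes were higher in Bright in 3 of 17 cases and in Dim in 0, with 6 and 0 at an unadjusted p under 0.05 and 3 and 0 adjusted over the list alone. Without Bright 3 they were 4 and 0, with Zfp36 gained (0.0445). Their mean was 110.2 FPKM in Bright 3, 74.8 and 83.7 in Bright 1 and 2, and 65.0 to 71.3 in the Dim libraries. Egr1 was at 101.0 ± 45.3 and 25.5 ± 0.735 FPKM (adjusted p = 0.00214, and 0.00139 without Bright 3). Ier2 was at 25.1 ± 15.1 and 6.96 ± 2.26 FPKM (adjusted p = 0.0296) and Nr4a1 at 35.1 ± 18.9 and 12.3 ± 0.344 (0.0204). Without Dim 1, Dim 2 or Dim 3 the calls were lost for Ier2 (0.0851, 0.126 and 0.0911) and Nr4a1 (0.091, 0.0902 and 0.0678), and for Ier2 also without Bright 1 (0.0535). The list passed (median 1.06, camera adjusted p = 0.00427), with adjusted p = 0.56 with an estimated correlation, and its median was 0.54 without Bright 3 (0.0203).

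Markers of somatic testis cells stood high in Bright 3 alone or nearly so. Leydig markers had a mean of 206.6 FPKM in Bright 3, and Insl3, a Leydig hormone (chromosome 8, 71689214 to 71690575), measured 1370 FPKM there and at most 0.197 in the other libraries. Sertoli markers had a mean of 59.8 FPKM in Bright 3 and 4.44 to 6.38 elsewhere, with Clu at 428.9 and 2.61 to 13.7. Peritubular myoid markers were at 17.4 against 0.746 to 1.66 FPKM, and stromal markers at 47.3 against 2.80 to 4.10. Macrophage markers were at 16.6 FPKM in Bright 3, 6.22 and 6.98 in Dim 1 and Dim 2, and 0.472 to 0.75 in Bright 1, Bright 2 and Dim 3. Lyz2, a macrophage lysozyme, followed them, at 65.4 FPKM in Bright 3, 21.2 and 24.6 in Dim 1 and Dim 2, and at most 0.890 in the rest. None of 13 Sertoli, 11 macrophage, 2 Leydig, 3 peritubular myoid or 3 erythroid markers tested was called by limma, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. Without Bright 3, the myoid marker Myl9 was called higher in Bright (log2 fold change 1.17, adjusted p = 0.0112), at 5.64 and 8.49 FPKM in Bright 1 and 2, 54.9 in Bright 3 and 2.18 to 2.91 in Dim. The Sertoli marker Wt1 was then called higher in Dim (-0.70, 0.0173), at 1.73 and 1.51 FPKM in Bright 1 and 2, 13.4 in Bright 3 and 3.14 to 3.49 in Dim. Erythroid markers were at 2.84 FPKM in Bright 3 and 0.134 to 1.61 elsewhere.

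The Sertoli list did not pass by camera (median 0.83, adjusted p = 0.158), although it did without Bright 1 (0.00807) or Bright 2 (0.0361), and its median was -0.17 without Bright 3. The macrophage list did not pass either (median -0.62, adjusted p = 0.725) until Bright 3 was left out (0.00785). Then it had adjusted p = 0.708 with an estimated correlation, and its markers were high in Dim 1 and Dim 2 but not in Dim 3. Of 7 stromal markers 1, Pdgfra, was higher in Bright, over all genes and adjusted over the list alone, and 0 in Dim at an adjusted or unadjusted p under 0.05. Pdgfra measured 6.13, 6.46 and 13.6 FPKM in Bright against 1.31 ± 0.189 in Dim (adjusted p = 0.00157, and 0.00186 without Bright 3). The stromal list did not pass (median 0.57, camera adjusted p = 0.146), but did without Bright 2 (0.039).

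Endothelial markers were higher in Bright for 5 of 6 tested members, over all genes and adjusted over the list alone, and 0 were higher in Dim at an adjusted or unadjusted p under 0.05. Kdr, a receptor for vascular endothelial growth factor, measured 2.35, 1.69 and 3.68 FPKM in Bright 1, 2 and 3 and 0.284 ± 0.0415 in Dim (adjusted p = 0.00197). Flt1, also such a receptor, was at 3.57 ± 0.751 and 1.26 ± 0.0842 FPKM (adjusted p = 0.00355). Cdh5 and Pecam1 were at 3.29 ± 2.34 and 2.51 ± 1.42 FPKM against 0.842 ± 0.071 and 0.863 ± 0.172 (adjusted p = 0.0443 and 0.0487). Without Bright 1, Dim 1, Dim 2 or Dim 3 both lost their calls (0.0515, 0.118, 0.125 and 0.127 for Cdh5; 0.0649, 0.109, 0.098 and 0.0995 for Pecam1), and Pecam1 also without Bright 3 (0.0532). The list passed (median 0.92, camera adjusted p = 0.0156, and 0.00858 without Bright 3), with adjusted p = 0.56 with an estimated correlation. Postmeiotic markers stayed low, with means of 1.23 to 1.36 FPKM in Bright and 0.502 to 0.769 in Dim. Of 3 tested, Tnp1 and Ldhc were higher in Bright and 0 in Dim at an adjusted or unadjusted p under 0.05, and all 3 were higher in Bright adjusted over the list alone. Tnp1, a transition protein gene, was at 5.32 ± 1.18 and 1.82 ± 1.03 FPKM (adjusted p = 0.019, and 0.0523 without Bright 2).

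**Figure D3:**
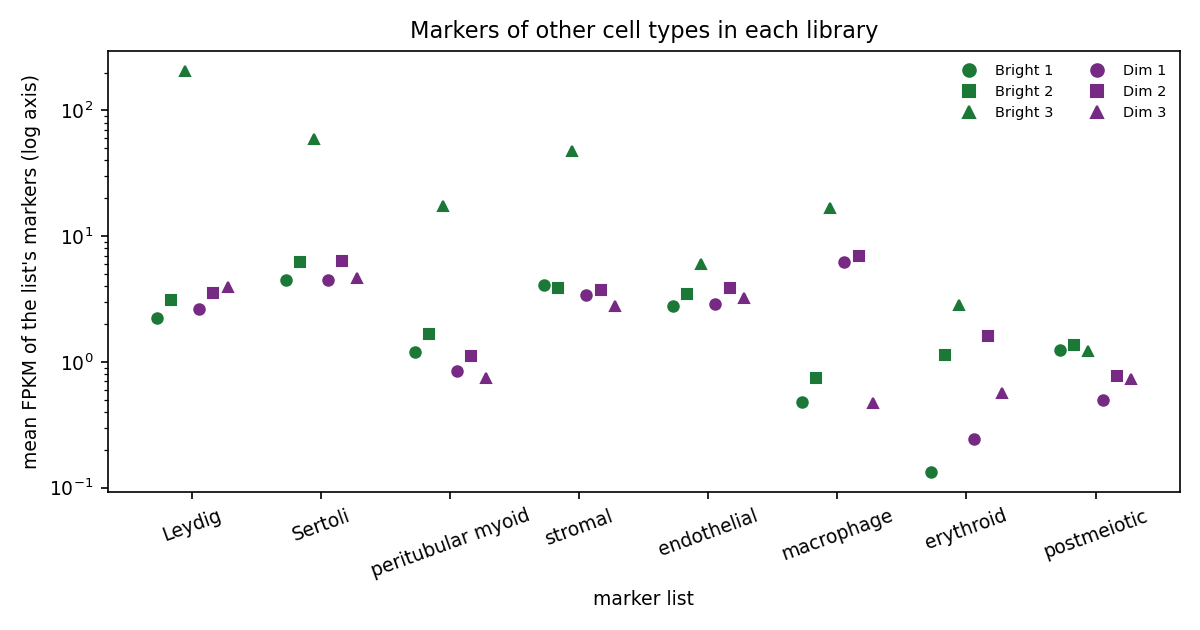
Mean FPKM of the markers of 8 other cell types on a log axis, in each Bright (green) and Dim (purple) library, with 1 marker shape per replicate number. Bright 3 stands above the other libraries for the Leydig, Sertoli, peritubular myoid, stromal and macrophage markers, with 206.6 FPKM for Leydig, and Dim 1 and Dim 2 lie at 6.22 and 6.98 for macrophage markers.

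Of the 23 lists tested, 12 passed with the preset correlation of camera, and 2 of these, the GDNF-responsive list and the MAPK and FGF feedback list, passed with an estimated correlation. By fry, 8 lists passed. Median, mean and test had the same sign for every list tested.

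The authors' own group table called 2462 genes at a q-value under 0.05, 1618 higher in Bright and 844 higher in Dim. Of these, 1956 were tested here, 1647 were called in the same direction and 0 in the opposite one. In that table Id4 had a log2 ratio of 3.03 (q = 0.000921). Of the genes named above as called, Foxc2 (q = 0.312), Neurog3 (0.242), Crabp2 (0.282), Aldh1a2 (0.144), Notum (0.23), Apcdd1 (0.323), Slc16a1 (0.0727), Pld6 (0.143), Tdg (0.226), Mbd2 (0.107), Tnp1 (0.0727) and Ldhc (0.0872) were not called there. Of those named and not called over all libraries, Sox3 (0.00232), Ndufv1 (0.00754), Zfp36 and Myl9 (0.000921 each) were. Of the 1618 genes higher in Bright, 1232 had Bright 1 and Bright 2 above every Dim library, and in 247 (15.3%) Bright 3 was the only Bright library above every Dim library. Examples of markers high in Bright 3 were Cyp17a1, a Leydig steroid enzyme, with a log2 ratio of 8.81, Dcn with 5.20 and Clu with 4.24, each at q = 0.000921; they were chosen after their values were seen. Of the 1608 genes called higher in Bright by limma, 0 had Bright 3 alone above every Dim library. This was close to fixed beforehand. The filter left out many such genes, with 2 of 9 Leydig markers tested, and the others varied too widely within Bright to be called readily. The authors' calls include genes not tested here, so the 0 cannot be set against the 15.3%. The authors' tables of single pairs, each with 1 library a side, called 35, 22 and 101 genes for the pairs numbered 1, 2 and 3. In the third, 100 of the 101 were higher in Bright, and 59 of these had Bright 3 alone above every Dim library.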

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

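The settings that leave out genes over 4 times higher in Bright 3, and that estimate the correlation without Bright 3, were chosen only after the results were seen. Leaving out those genes from the finished fit gave 3014 calls in place of 3016. Nothing was refitted, and genes high in Bright 3 alone vary so widely within Bright that few could be called. This count therefore does not show how Bright 3 affects the other calls. With Bright 3 itself left out, 2263 of the 3016 were kept. The count stayed within 1.5 times of 3016 under both pseudocounts (3018 and 2909), no filter (2334, with more genes tested), a filter of 5 FPKM (2161, with fewer), quantile normalization (3152), median of ratios scaling (3057) and limma without trend (2900). No called gene reversed in any of these settings, and the share of calls higher in Bright ran from 49.2% (quantile) to 56.9% (no filter). Leaving out 1 library, with fewer samples, gave 1957 (without Dim 2) to 2603 (without Bright 2) genes, with 849 to 1225 higher in Dim for the same libraries. Without Dim 3 there were 1973, with 878 higher in Dim. A log2 fold change of at least 1 left 971 genes (648 higher in Bright, 323 in Dim), and an adjusted p under 0.01 left 1399 (829 and 570), both by construction. The authors' q-value gave 844 genes higher in Dim, and the cause was not tested. With the replicate number as a block there were 5453 genes (2607 and 2846), and 5808 (2638 and 3170) with quantile normalization; the cause was not tested. The labels do not say that libraries with the same number share animals. The differences from the group mean correlated at 0.435, 0.511 and -0.194 for same-numbered libraries, and 4 of the 6 libraries correlated best with their own number, a hint from the data and not the design, so the block was not used for the results. Under the block Cited1 (0.0909), Ly6k (0.169), Ier2 (0.185), Ier3 (0.165), Nr4a1 (0.0771) and Cdh5 (0.0537) were not called, and Mycn (0.0415), Ndufv1 (0.00341), Tdrd5 (0.0402) and Asz1 (0.0447) were. The block kept 2973 of the 3016 calls. Cdh1 (0.000108), Tcf4 (0.0019), Ndufv2 (0.000898), Tet3 (0.000143) and Rps4x (0.000244), whose calls were lost with some libraries left out, were called there at lower adjusted p. The oxidative phosphorylation list also passed with the block (camera adjusted p = 0.000366). Lists that passed fell from 12 to 2 with an estimated correlation, and to 0 with that and Bright 3 left out. With fry 8 lists passed. Among them were the stem-cell-associated (adjusted p = 0.00021), cholesterol synthesis (0.00105), differentiating (0.00816), glycolysis (0.0104), retinoic acid response (0.0424) and endothelial (0.0477) lists.

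For single named genes, 824 values under alternatives other than a left-out library kept their direction and side of the threshold, 43 lost the call and 2 gained it. With a library left out these numbers were 510, 76 and 2. For lists they were 138, 19 and 0, and 122, 8 and 8. With no filter, 17 named genes lost their call, at adjusted p of 0.0513 (Zbtb16) to 0.12 (Pecam1). They included Cdh1 (0.0658), Notum (0.0661), Tcf4 (0.115), Ndufv2 (0.111), Rps4x (0.0637), Ier2 (0.0623), Nr4a1 (0.0578), Cdh5 (0.11) and Tnp1 (0.0623). Neurog3 lost its call with no filter (0.0999), median of ratios scaling (0.062) or limma without trend (0.0504), and Nanos3 was called in 2 settings, both with the block; adjusted p over these alternatives ran from 0.0103 to 0.0999 and from 0.0138 to 0.153. With fry, which does not compare a list with other genes, the meiotic (0.0727), S phase (0.153), oxidative phosphorylation (0.431) and immediate early (0.171) lists did not pass. S phase also missed with quantile normalization (0.113) and the filter of 5 FPKM (0.0581), oxidative phosphorylation with quantile normalization (0.0501), and retinoic acid response with the block (0.0616); over all alternatives other than a left-out library these 5 lists ran up to 0.618, 0.741, 0.772, 0.56 and 0.395. The planned count-based tests were not run because the values are FPKM, and the authors' significance status was read from the q-value. Genes under 1 FPKM in 4 or more libraries were tested only with no filter.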

Other observations

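The tests in this part were all chosen only after the results were seen. Chromosome 13 held few genes higher in Dim, 22 of 455 tested (4.8%) against 10.7% elsewhere (Fisher's exact test, p = 1.62e-05, adjusted p = 0.00065 over 40 tests, with genes that are not independent). Chromosome 17 was also low, with 6.8% of 674 (adjusted p = 0.013), and chromosome 4 high, with 14.1% of 882 against 10.2% (adjusted p = 0.0125). Among the same 40 tests, genes higher in Bright were more frequent on chromosome 1, with 15.6% of 743 against 11.8% elsewhere (adjusted p = 0.0197). They were less frequent on chromosome 7, with 9.1% of 1059 against 12.2% (0.0188), and on chromosome 5, with 9.1% of 910 against 12.2% (0.0337).

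In Bright 3, 758 genes were over 4 times higher than in every other library, against 1 to 6 genes in each of the others. A wrong label of Bright 3 is argued against, since over 981 genes called without it at a log2 fold change of at least 1 Bright 3 lay at a median position of 0.96 between Dim at 0 and the other Bright libraries at 1, with quartiles of 0.8 and 1.13. RNA of whole adult testis is argued against as well, since the postmeiotic markers in Bright 3 were at 0.9 times the highest other library. RNA of somatic testis cells remains a candidate explanation, since 60% of 65 markers of 6 somatic cell types (39, with 8 of 9 Leydig, 11 of 16 Sertoli, 7 of 8 peritubular myoid, 7 of 10 stromal, 4 of 10 endothelial and 2 of 12 macrophage) were among these genes, against 5% of 15181 genes, with Insl3 at 1370 FPKM, Clu at 428.9 and Dcn at 151.2; 31 of the 65 reached 1 FPKM in Bright 1 or Bright 2 too. Some germ-cell lists were lower in Bright 3 than the mean of Bright 1 and 2. The median log2 difference was -0.27 over 25 meiotic genes and -0.35 over 18 piRNA and transposon silencing genes. By mean log2(FPKM + 1), the undifferentiated (5.04 against 5.30 and 5.13), progenitor (4.26 against 4.67 and 4.65) and differentiating (4.94 against 5.30 and 5.29) lists were lower too. The stem-cell-associated (4.22 against 4.12 and 4.32) and GDNF-responsive (4.829 against 4.745 and 4.856) lists stayed level, so the drop was not general. A gate on the germ-cell reporter should leave out cells without it, but its purity was not measured here. No biological explanation was tested, because the design gives Bright 3 no group of its own.

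Over all libraries together, 1214 genes differed between replicate numbers in a fit with the group and the number as terms. Transcript length may account for much of the difference between numbers 1 and 2, since across these genes it correlated by rank with the log2 difference at 0.62 in Bright and 0.6 in Dim. The genes were picked for a number effect shared by the groups, so these values are not separate results. Over all tested genes, length correlated with the deviation from the group mean at 0.46 in Bright 1 and -0.42 in Bright 2. In Dim 1 and Dim 2 it did so at 0.52 and -0.48. With the Bright to Dim change, length correlated at 0.043 over all tested genes. Replicate 3 differed by over 2 times from both other numbers in both groups at 9 genes, and 44.4% of them lay within 5000000 bases of another, against a 95th percentile of 22.2% in 10000 random sets (permutation p = 0.011), with Platr25, Gm26639, Gm10772 and Gm26715 on chromosome 13. A genetic variant carried by the mice of the replicate 3 libraries is a candidate explanation for these. The random sets came from all tested genes, unmatched for gene type or local clustering, so nearness alone cannot tell a variant from other causes. Length cannot be told apart there either, since the correlations of 0.07 in Bright and 0.07 in Dim rest on 9 genes, with an interval of about ± 0.8. A variant itself was not tested, because the labels do not say which mice gave which library.

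Endothelial markers were higher in Bright 1 and Bright 2 too, where the 5 called ones summed to 11 and 9.61 FPKM, against 3.76 to 4.15 in Dim and 21.1 in Bright 3. RNA of endothelial cells in these libraries cannot be told apart from expression of these genes by the Bright germ cells. It would raise all 10 markers, and 6 of the 10 were higher in both libraries than in every Dim library. The 4 untested ones (Emcn, Esam, Cldn5 and Tie1) summed to 0.309 and 0.414 FPKM there, no higher than the 0.421 to 0.739 in Dim, and to 17 in Bright 3, which goes against endothelial RNA in Bright 1 and Bright 2. It excludes nothing, because these 4 were left untested for their low values and the ratio between markers in such cells is not known; Egfl7 was at 16.7 and 24.9, against 24.1 to 34.4 in Dim, which would hide a small share.

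Of the 10 splits of the 6 libraries into groups of 3, 1, the real one, gave as many as 3016 genes, and the highest of the others gave 14. The splits are too few for a share under 0.05.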
